A study of Sus scrofa with 22 samples.

How the data were processed

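The series measured RNA levels in slices of distal small intestine and colon of piglets aged 19 days. Each of the 22 arrays was a 2-colour array that carried the RNA of 1 tissue sample of 1 piglet, labelled with Cy5, against a common reference pool of 88 samples, labelled with Cy3. The dyes were not exchanged on any array, so a dye effect that is the same on every array leaves the differences between arrays unchanged but shifts the level against the pool.

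The deposited values are log2 ratios of the sample over the reference pool. Per the labels, the authors processed the arrays with limma, with no version given. The base of the logarithm, the background correction, the spot filter and the normalization are not stated, and the values were taken as already normalized log2 ratios, as limma writes them. A fold change printed here rests on that base. The table holds no channel intensities, so no filter on signal over background was possible, and the number of arrays limits the precision.

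The value table had 20736 spots, of which 787 were empty. Of the empty spots, 273 were missing on every array and 514 held 0 or nothing on every array. These were left out, and the other 19949 probes had a value on at least 1 array. A gene symbol was given for 178 probes, with 175 different symbols, which is 0.892% of the probes with a value. The other probes have no name in the tables at hand and were tested but not named. Spot positions were read from the order of the table as 48 print blocks of 18 by 24 spots, a layout that was inferred and is not stated.

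Piglets were grouped by the labels into control and IUGR, and each labelled pair held 1 of each. All 7 pairs share a labelled birth date within the pair. What else the pairs were matched on is not stated. As a check, the correlation over probes of the members of a pair, after the mean of their group was removed, ran from -0.385 to 0.328 in the distal small intestine and from -0.306 to 0.615 in the colon. The block correlation estimated by limma was -0.015 in the distal small intestine and 0.075 in the colon.

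Differences were tested per probe with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3, with Benjamini-Hochberg adjustment and a threshold of 0.05. IUGR was compared with control within each tissue, with the pair as a block, for probes measured in both members of at least 4 pairs. Colon was compared with distal small intestine in the 8 piglets with both tissues, with the piglet as a block, for probes measured in both tissues of at least 6 piglets. The difference of the IUGR effect between the tissues was tested on the per-piglet difference of the tissues, with the pair as a block. Male and female piglets were compared in each tissue with the group as a covariate. Body weights were compared within pairs by exact sign flips, two-sided. The models were tested on simulated data with the same designs, spread per probe and missing values and with independent noise, in which 50 probes were changed at each of 4 sizes. At a simulated log2 change of 0.5, the fits recovered 48 of 50 probes for IUGR in the distal small intestine, 35 for IUGR in the colon, 47 for the tissues and 9 for the difference of the IUGR effect. At 0.25, near the size of many differences reported for named genes, they recovered 8, 2, 14 and 0. The changed probes of all 4 sizes stood in 1 simulated set, which eases the Benjamini-Hochberg threshold. Where few or no probes pass, fewer changes of these sizes would be recovered. In the real IUGR fits, probe 20488 at 0.45 in distal small intestine and probe 12623 at 0.69 in colon did not pass (limma adjusted p = 0.652 and 0.944). A lack of calls therefore does not exclude changes of 0.5.

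The comparisons, 31 gene lists, the rule for named genes and most alternatives were fixed before the data were examined. The rule took, for each comparison, up to 10 named genes per direction that passed the threshold with the same sign in every pair or piglet, by size. Empty places went to the named genes with the smallest unadjusted p and the same sign in every pair or piglet, reported as not passing. Up to 4 members were added for each list that passed or that held a member past the threshold. LEPR, PSMB8 and GOT1 in the distal small intestine, QDPR and LIF in the colon, and CD4, IL2, LIF, CAV1, CCR9, SLC15A1 and RXFP4 between the tissues were chosen after their values were seen. The same holds for members named with a list that neither passed nor held a member past the threshold, and for each unnamed probe given by its number.

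None of the 31 gene lists fixed in advance had 5 measured genes, and 15 had any, with at most 3. They held 1006 genes, of which 20 were measured, so these were tested as 1 group of genes and not list by list. In their place, 7 lists were made from the names in the probe table, after the names were seen and before any value of a named gene was examined. These were cytokines and chemokines, immune cell receptors and surface proteins, innate defence proteins, epithelial digestion, transport and conversion, peptide hormones and their receptors, widely used cell functions, and genes of the germ line, eye, skin, mammary gland or striated muscle. They were tested with limma camera at a preset correlation of 0.01 against all other probes, with camera at an estimated correlation and with fry as alternatives.

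Alternatives for the probe tests were no block, pair as a random block, sex as a covariate, centring, quantile normalization, array weights, complete probes, leaving out the 50% of probes with the smaller spread, robust eBayes, a joint fit of all arrays, averaging of probes and leaving out each pair. After the data were seen, removal of the median of each print block and of a local median in a window of 7 by 7 spots were added, since neighbouring spots correlated. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6 in Python 3.11.15.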

Results

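RNA levels were measured in the gut of 14 suckling piglets, 7 with intrauterine growth restriction (IUGR, poor growth before birth) and 7 controls, in 7 labelled pairs of 1 IUGR and 1 control piglet. Distal small intestine was measured in 6 control and 6 IUGR piglets, and colon in 5 control and 5 IUGR piglets. Both tissues came from 8 piglets of 4 pairs. Each array gave a log2 ratio to the same reference pool for 19612 to 19878 probes. The array medians lay between -0.018 and -0.00095, and the SD over probes between 0.26 and 0.46. Pearson's r over probes between pairs of arrays ran from 0.498 to 0.907 with a median of 0.727, and 72.8% of the total variance lay in probe means shared by all arrays. Neighbouring spots correlated within every array, with r between 0.0562 and 0.452, against at most 0.0108 in size after shuffling. Many of the 178 probes with a gene symbol lie side by side on the array, which bears on the named genes below. In the inferred layout, the named probes take the same few places of each print block that holds them. A test of a list of named genes against all other probes therefore also compares those places with the rest of the blocks.

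IUGR piglets were lighter than their control partner at birth and at death in 7 of 7 pairs. The labels give no unit for the weights. Weight at birth was 1.38 ± 0.0522 (SD, n = 7) in control and 0.963 ± 0.0812 (SD, n = 7) in IUGR piglets, a mean within-pair difference of -0.42 and 69.6% of the control weight (exact sign-flip p = 0.0156, two-sided, the smallest that 7 pairs allow). Weight at death was 6.78 ± 0.902 (SD, n = 7) in control and 4.65 ± 0.425 (SD, n = 7) in IUGR piglets, which was 69.3% of the control weight (exact sign-flip p = 0.0156). The weight at death over the weight at birth was 4.92 ± 0.760 (SD, n = 7) in control and 4.86 ± 0.624 (SD, n = 7) in IUGR piglets. Its mean within-pair difference was -0.055 ± 0.44 (SD, n = 7 pairs, exact sign-flip p = 0.734). IUGR piglets are presumably chosen by birth weight, so that difference describes the groups.

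**Figure D1:**
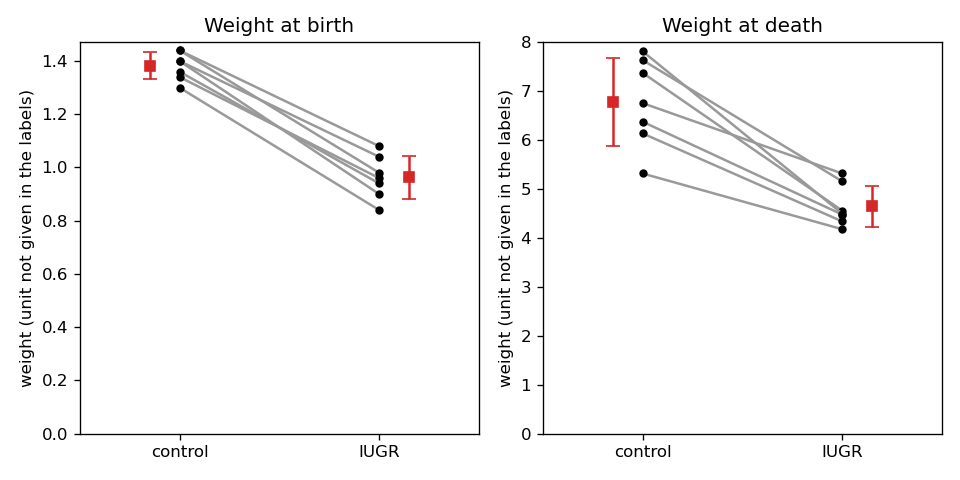
Weight at birth (left) and at death (right) of control and IUGR piglets, in the unit of the labels, which is not given. Each grey line joins the members of 1 of 7 pairs, and red squares with bars give the mean and SD of each group, with means at birth of 1.38 and 0.963. Every IUGR piglet lies below its partner in both panels.

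In the distal small intestine, the comparison of IUGR with control piglets asked which transcripts still differed at 19 days of age, and no named gene passed the test. PAG6, a pregnancy-associated glycoprotein of the placenta, was 0.26 higher on the log2 scale in IUGR piglets (SE 0.062, adjusted p = 1.0, 6 of 6 pairs), with a mean of 0.0085 ± 0.20 (SD, n = 6) in control and 0.27 ± 0.16 (SD, n = 6) in IUGR piglets. GAD2, a glutamate decarboxylase that makes the transmitter GABA, was 0.20 higher (SE 0.075, adjusted p = 1.0, 6 of 6 pairs), and 0.13 higher without pair 11. Of the genes chosen after their values were seen, the leptin receptor LEPR differed by -0.29 (SE 0.088, lower in 5 of 6 pairs), the immunoproteasome subunit PSMB8 by 0.19 (SE 0.081, higher in 4 of 6 pairs) and the cytosolic aspartate aminotransferase GOT1 by -0.36 (SE 0.21, lower in 4 of 6 pairs), none of them past the threshold. Without pair 25 GOT1 differed by -0.19 and without pair 11 by -0.21. PAG6 and PSMB8 lie within 5 neighbouring spots with ASIP, CEND1 and LTA, all higher in IUGR piglets, and after removal of the local median on each array PAG6 differed by 0.16 and PSMB8 by 0.068.

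Of 19719 probes tested in the distal small intestine, limma found 0 past the threshold, with 536 at an unadjusted p under 0.05 (2.72%, 272 higher and 264 lower) and a smallest adjusted p of 0.652. Over the 178 named probes alone, 0 passed, and 5 were at an unadjusted p under 0.05. The 95% intervals of all 178 named probes lay within 1 log2 unit of 0, and those of 173 within 0.5. The median standard error over probes was 0.070.

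None of the 7 gene lists made from the probe names passed in the distal small intestine by camera, and no member of any list passed over all probes or over its list alone. The innate defence proteins had 8 of 12 members higher in IUGR piglets (median 0.033, adjusted p = 0.130), among them CRP at 0.15 and the collectin MBL2 at 0.12. Cytokines and chemokines had 9 of 12 higher (median 0.056, adjusted p = 0.130), with IL1A at 0.24, and without pair 11 this list passed as higher at the preset correlation (adjusted p = 0.00317). With all pairs and the estimated correlation of 0.0621 its adjusted p was 0.4661. IL1A and its list member IL17A (0.16) are neighbouring spots, next to ULBP1 of another list, which was higher too (0.12). No list was tested with the local median removed, so a trend by position on the array cannot be set apart from a change of the list. Epithelial digestion, transport and conversion had 9 of 15 higher, the immune cell receptors and surface proteins 11 of 19, the tissue-restricted genes of germ line, eye, skin, mammary gland or striated muscle 15 of 28, and widely used cell functions 9 of 20 (adjusted p = 0.368, 0.368, 0.368 and 0.524). Widely used cell functions had a median of -0.0041 and a mean of -0.0070, whereas the test direction was up. Peptide hormones and their receptors had 10 of 16 higher with a median of 0.026, whereas their mean was -0.018 and the test direction was down (adjusted p = 0.868). Among the 20 measured genes of the lists fixed in advance, 0 passed adjusted over the list alone in limma, with 1 at an unadjusted p under 0.05.

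In the colon, the same question gave 12 named genes with the same sign in 5 of 5 pairs, none of which passed the test. Higher in IUGR colon were UTS2, the vasoactive peptide urotensin, by 0.61 (SE 0.23), ELSPBP1, a sperm-binding protein of the epididymis, by 0.33 (SE 0.099), KCNN4, a calcium-activated potassium channel of secreting epithelia, by 0.24 (SE 0.077), and PSMB8 by 0.24 (SE 0.077). LEPR and the integrin chains ITGA2B and ITGB1 were higher by 0.19, 0.16 and 0.17. CYP8B1, an enzyme of bile acid synthesis, differed by -0.20 (SE 0.083), TNFSF8 by -0.18, the peptidoglycan recognition protein PGLYRP2 by -0.15, PPYR1 by -0.14 and the gonadotropin receptor FSHR by -0.060. The adjusted p was 0.944 for each of the 12. Among 177 named probes, the same sign in all of 5 pairs is common by chance, so it is no evidence of a change by itself. Of the genes chosen after their values were seen, QDPR, which recycles tetrahydrobiopterin, was 0.43 higher and the cytokine LIF 0.32 higher, each in 4 of 5 pairs and neither past the threshold. QDPR and ELSPBP1 are neighbouring spots, and with the local median removed they differed by 0.26 and 0.19, and PSMB8 by 0.082. UTS2 was 0.30 higher without pair 25 and ITGB1 0.093 without pair 12, ELSPBP1 0.20 after quantile normalization, and PSMB8 0.14 with the median of each print block removed.

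Of 19683 probes tested in the colon, limma found 0 past the threshold, with 590 at an unadjusted p under 0.05 (3.00%, 471 higher and 119 lower) and a smallest adjusted p of 0.944. After quantile normalization the balance at this level was 291 higher and 223 lower. Over the 177 named probes alone, 0 passed, and 9 were at an unadjusted p under 0.05. The 95% intervals of 176 of the 177 named probes lay within 1 log2 unit of 0, with UTS2 the exception, and the median standard error over probes was 0.090.

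None of the 7 lists passed in the colon by camera, and no member passed over all probes or over its list alone. Cytokines and chemokines had 8 of 12 members higher in IUGR piglets, innate defence proteins 9 of 12 with FCN1 at 0.14 and the defensin DEFB1 at 0.14, peptide hormones and their receptors 10 of 16, and widely used cell functions 12 of 20 (adjusted p = 0.612 for each of the 4). Of the innate defence proteins, PGLYRP2 had the smallest p and went the other way, at -0.15 and lower in 5 of 5 pairs. Immune cell receptors and surface proteins had 8 of 19 higher, and the tissue-restricted genes 14 of 29 with a median of -0.013, a mean of 0.014 and a test direction of down (adjusted p = 0.612 for both). Epithelial digestion, transport and conversion had 8 of 15 higher, with a positive median and mean and a test direction of down (adjusted p = 0.713). Among the 20 measured genes of the lists fixed in advance, 0 passed adjusted over the list alone in limma, with 1 at an unadjusted p under 0.05.

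Between colon and distal small intestine of the same 8 piglets, 4 named genes passed the test. PI3, the protease inhibitor elafin of mucosal surfaces, differed by -0.76 on the log2 scale (SE 0.062, adjusted p = 8.99e-05, lower in colon in 8 of 8 piglets), with means of -0.37 ± 0.31 (SD, n = 8) in colon and 0.38 ± 0.30 (SD, n = 8) in distal small intestine. INHA, the alpha subunit of inhibin, was higher in colon by 0.44 (SE 0.049, adjusted p = 6.44e-04, 8 of 8 piglets), with means of -0.31 ± 0.21 (SD, n = 8) in colon and -0.75 ± 0.13 (SD, n = 8) in distal small intestine. PR39, a cathelicidin antimicrobial peptide of neutrophils, differed by -0.25 (SE 0.057, adjusted p = 0.0407, lower in colon in 8 of 8 piglets), and PLA2G1B, a secreted phospholipase first known from the pancreas, was higher by 0.24 (SE 0.057, adjusted p = 0.0465, 8 of 8 piglets). PR39 missed the threshold when any 1 of the 4 pairs was left out, at -0.29 to -0.19 (SE 0.057 to 0.074), with 2 fewer piglets and a smaller difference only without pairs 21 (-0.19) and 25 (-0.24). With the local median removed it missed at a smaller difference of -0.18 (SE 0.048, adjusted p = 0.0659). PLA2G1B missed it when any 1 of the pairs was left out, at 0.22 to 0.26 (SE 0.056 to 0.073). It also missed with the median of each print block removed (0.20, SE 0.053) or the local median removed (0.18, SE 0.051), where the difference was smaller, and with the less variable probes left out, where it stayed at 0.24 and the SE was larger (0.078).

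**Figure D2:**
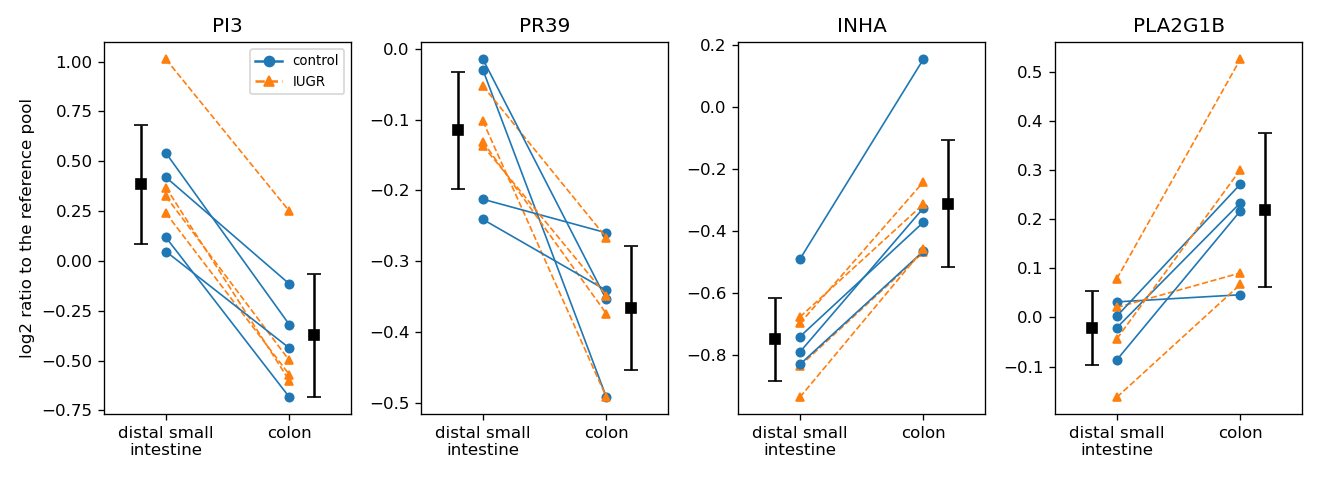
Log2 ratio to the reference pool (vertical axis) of PI3, PR39, INHA and PLA2G1B in distal small intestine and colon, with 1 line per piglet for 8 piglets, blue circles for control and orange triangles for IUGR. Black squares with bars give the mean and SD over the 8 piglets. PI3 and PR39 were lower in colon and INHA and PLA2G1B higher in colon in 8 of 8 piglets.

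Other genes that the rule named between the tissues did not pass. The ligand TNFSF4, which co-stimulates T cells, was 0.46 higher in colon (adjusted p = 0.103), and the estrogen sulfotransferase SULT1E1, the prolactin receptor PRLR, the gut hormone ghrelin (GHRL), IL12RB2 and the protamine PRM2 differed by -0.24, -0.22, -0.17, -0.14 and -0.13 (adjusted p between 0.0748 and 0.253), each in 8 of 8 piglets. The protegrin NPG4, an antimicrobial peptide, differed by -0.33 (adjusted p = 0.0681, 7 of 8 piglets). Of the genes chosen after their values were seen, CD4 differed by -0.31, IL2 by -0.22, LIF by 0.55 and the caveolar protein CAV1 by 0.18 (adjusted p = 0.0633, 0.0533, 0.0938 and 0.141). PR39, IL2 and GHRL are neighbouring spots, and with the local median removed IL2 differed by -0.13 and GHRL by -0.084, and PRM2 by -0.069. Without pair 21, TNFSF4 was 0.25 and LIF 0.35 higher in colon. Of genes known to differ along the gut, chosen after their values were seen, the small intestinal peptide transporter SLC15A1 differed by -0.017, the homing receptor CCR9 by -0.13 and RXFP4, the receptor of a hindgut hormone, by 0.18 (7 of 8 piglets), none past the threshold. SLC15A1 was the 1 measured gene of the small intestine markers fixed in advance, and 0 colon markers were measured. Its means were 0.16 ± 0.12 (SD, n = 8) in distal small intestine and 0.14 ± 0.15 (SD, n = 8) in colon. The planned check of the tissue labels and the direction of the ratio by known markers therefore gave them no support.

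Of 19701 probes tested between the tissues, 619 passed, 360 higher and 259 lower in colon, with 3591 at an unadjusted p under 0.05 (18.2%). Over the 177 named probes alone, 2 passed, PI3 and INHA (adjusted p = 1.70e-05 and 2.03e-04), and 32 were at an unadjusted p under 0.05. Of the 619, 24 differed by more than 2-fold, 10 higher and 14 lower. The unnamed probes with the smallest p per direction were 10707, which differed by 1.84 (SE 0.056, higher in colon in 8 of 8 piglets), 4423 by 1.24, 980 by -1.46 (lower in colon in 7 of the 7 piglets measured) and 6941 by -1.21. Without the piglet as a block 1000 probes passed, 593 of them among the 619, and leaving out 1 of the 4 pairs left 177 (pair 11), 188 (pair 12), 208 (pair 21) or 286 (pair 25).

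None of the 7 lists passed between the tissues by camera. With fry's test of differences in either direction, which does not compare a list with other genes, innate defence proteins (adjusted p = 1.85e-06) and cytokines and chemokines (0.00210) passed and the other 5 did not (0.0549 to 0.357). All named genes together passed that test too (unadjusted 1.94e-05), so passing was not particular to these lists, and in camera with an estimated correlation the adjusted p of both lists was 0.961. Of the 12 members of the innate defence list, PI3 and PR39 fell in colon. PLA2G1B, placed in this list although first known from the pancreas, rose. Over the list alone 5 passed, while the list had 7 members higher, a median of 0.069 and a mean of -0.049 (adjusted p = 0.957). No cytokine or chemokine passed over all probes, but 4 of 12 did so over the list alone, namely IL2, LIF, TNFSF4 and IFN-DELTA-1 (list adjusted p = 0.957, median -0.063, mean 0.016). Of the immune cell receptors and surface proteins, 12 of 19 were lower in colon, with FAS at -0.20, and CD4 passed over the list alone (adjusted p = 0.339). Epithelial digestion, transport and conversion had 8 of 15 lower with a median of -0.017 and a mean of 0.015 (adjusted p = 0.967), peptide hormones and their receptors 9 of 16 lower (adjusted p = 0.957), widely used cell functions 13 of 20 higher (adjusted p = 0.957) and the tissue-restricted genes 14 of 28 higher (median -0.0014, mean 0.0046, adjusted p = 0.9746). Over these 4 lists alone 0 members passed in limma, with 2, 3, 3 and 3 at an unadjusted p under 0.05. Among the 20 measured genes of the lists fixed in advance, CD4 passed adjusted over the list alone (0.0496), and 0 passed over all probes in limma, with 5 at an unadjusted p under 0.05. CD4 lay just under the threshold, and differed by -0.25 with the local median removed, where the 20 genes were not adjusted again. Over the alternatives its limma adjusted p over all probes ran from 0.0191 to 0.321.

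The difference of the IUGR effect between colon and distal small intestine, in the 4 pairs with both tissues, asked whether IUGR and control piglets differed alike in both, and no named gene passed over all probes. ITM2A, an integral membrane protein, had the smallest p of the named genes, with a difference of 0.78 (SE 0.11, adjusted p = 0.260, 4 of 4 pairs), from an IUGR effect of 0.37 ± 0.36 (SD, n = 4) in colon and -0.41 ± 0.52 (SD, n = 4) in distal small intestine. Over all pairs of each tissue, the IUGR effect on ITM2A was 0.20 in colon (SE 0.16, higher in 3 of 5 pairs) and -0.18 in distal small intestine (SE 0.18, lower in 4 of 6 pairs), neither past the threshold. The effect was also more positive in colon, in 4 of 4 pairs, for CDKN2B, an inhibitor of the cell cycle, by 0.62, LIF by 0.57, LEPR by 0.52, the lipid-antigen presenter CD1.1 by 0.50, MAOA, which breaks down monoamines, by 0.47, the checkpoint ligand PDCD1LG2 by 0.47, SRY by 0.44, SCAMP1 by 0.43 and the neuropeptide NPW by 0.43. It was more negative in colon for GAD2 by -0.49, ACADS, an enzyme of fatty acid oxidation, by -0.40, CD4 by -0.37, CYP8B1 by -0.35, RXFP4 by -0.34, PLCZ1 by -0.33, MMP20 by -0.32, HRH4 by -0.31, XCR1 by -0.30 and SULT1E1 by -0.28. Their adjusted p lay between 0.263 and 0.323. The same sign in all of only 4 pairs is common by chance among this many named probes. LIF and SRY are neighbouring spots, which differed by 0.56 and 0.45 with the local median removed, while CD4 then differed by -0.23 and HRH4 by -0.17. SRY lies on the Y chromosome, whereas both piglets of pair 21 were female. In pair 11 the IUGR piglet was male and its partner female. The value of this probe can therefore not be read as an IUGR effect on SRY RNA. PDCD1LG2 differed by 0.14 after quantile normalization (adjusted p = 0.575), and RXFP4 by -0.22 without pair 11.

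Of 19701 probes tested for this difference, limma found 0 past the threshold, with 2962 at an unadjusted p under 0.05 (15.0%, 2171 higher and 791 lower) and a smallest adjusted p of 0.260. After quantile normalization the balance at this level was 1169 higher and 1138 lower. Without pair 25, 2014 probes passed, whereas the other 11 of 12 alternatives gave 0. Of the 2014, 1684 had a more positive effect in colon, with ITM2A, CDKN2B, NPW, PDCD1LG2 and the SRY probe among them. The other 330 had a more negative one, with GAD2 and ACADS among them. These names rest on that 1 fit. With all 4 pairs, exchanging the members of pair 25 put 664 probes past the threshold, where the real split put 0.

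None of the 7 lists passed for this difference by camera, with an adjusted p of 0.783 for each. The effect was more positive in colon for 10 of 16 peptide hormones and their receptors (median 0.067) and 12 of 20 widely used cell functions (median 0.043), and both lists passed with fry (adjusted p = 0.0415 for each), which does not compare a list with other genes. With an estimated correlation in camera neither did (adjusted p = 0.844). With fry's test of differences in either direction, widely used cell functions (adjusted p = 1.39e-06), immune cell receptors and surface proteins (6.89e-04) and the epithelial list (0.0225) passed, and the other 4 did not (0.106 to 0.248). All named genes together passed fry as well (unadjusted 0.0248, and 0.00752 in either direction), so passing was not particular to these lists. Of the immune cell receptors and surface proteins 13 of 19 were more negative, and PDCD1LG2 passed over that list alone. The effect was more positive for 7 of 12 innate defence proteins, 6 of 12 cytokines and chemokines (median -0.033, mean 0.0047, direction down), 8 of 15 of the epithelial list (median 0.065, mean 0.023, direction down) and 14 of 28 tissue-restricted genes (median -0.0087, mean 0.0072, direction down). Among the 20 measured genes of the lists fixed in advance, 0 passed adjusted over the list alone in limma, with 5 at an unadjusted p under 0.05.

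Across 19122 probes measured on every array, the mean IUGR effects of the tissues in the 4 shared pairs correlated negatively, with Pearson's r = -0.413 and Spearman's rho = -0.395. Probes are not independent replicates, and the pairs allow 8 sign patterns, of which the real one was the most negative, with the other patterns between -0.396 and 0.308. With different pairs in each tissue, 6 divisions gave r between -0.214 and 0.131, with a median of -0.140 and 1 of the 6 above 0. In each of them 15 to 31 of 32 sign patterns lay as far from 0, and all share pairs 3 and 4 in distal small intestine and pair 23 in colon, so they are not independent.

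**Figure D3:**
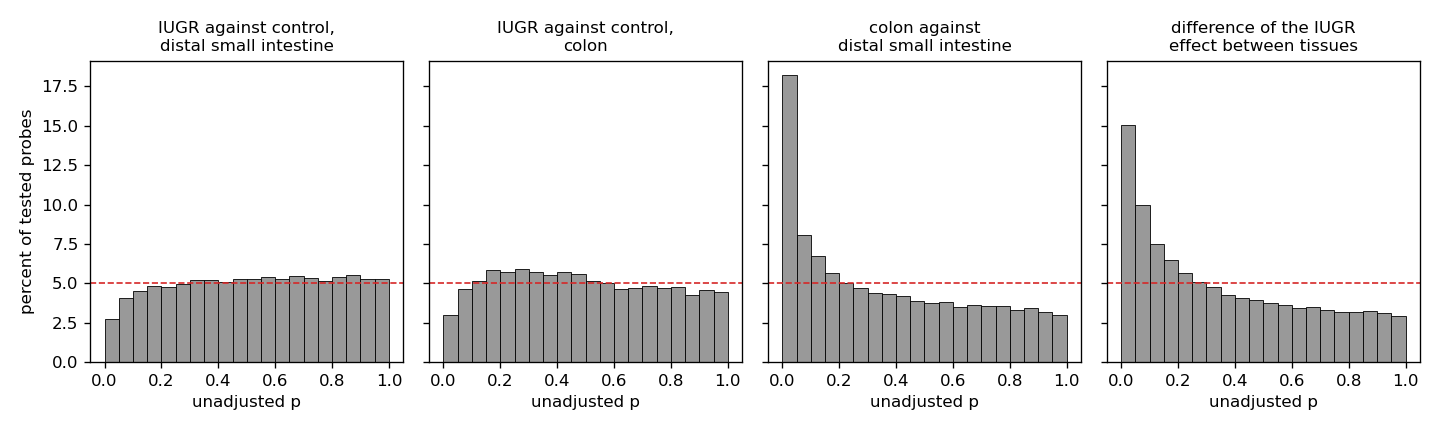
Percent of tested probes (vertical axis) by unadjusted limma p in 20 bins for IUGR against control in distal small intestine and in colon, colon against distal small intestine, and the difference of the IUGR effect between the tissues. The red dashed line is at 5%, the level without any difference. Under 0.05 lie 2.72%, 3.00%, 18.2% and 15.0% of the probes.

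Male and female piglets were compared as a check of the labels. SRY, the testis-determining gene of the Y chromosome and the one measured gene of the sex-linked list, differed between males and females by -0.028 in distal small intestine (SE 0.095) and 0.37 in colon (SE 0.13, adjusted p = 0.252), so it did not separate the sexes. In the distal small intestine 1 of 19719 probes passed, the unnamed probe 9480, with a difference of males from females of -0.56 (SE 0.063, adjusted p = 0.0138), with means of -0.29 ± 0.089 (SD, n = 6) in males and 0.27 ± 0.11 (SD, n = 6) in females. In the colon probe 9480 differed by -0.62 (SE 0.094, adjusted p = 0.108), and limma found 0 of 19683 probes past the threshold, with 2724 at an unadjusted p under 0.05. The 6 male and 6 female arrays of distal small intestine did not overlap at this probe, nor did the 6 male and 4 female arrays of colon.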

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

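The counts over other splits of the samples were planned before they were seen, those by sex that kept the pairs only after the other splits by sex, whereas the tests of array position, of single pairs or arrays and of neighbouring spots were chosen after the result was seen.

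In 15 of 184 groups of 4 to 10 samples (8.15%), 1 sample lay far from the others by Dixon's gap test, and chance gives about 1 in 20. Among measures of whole arrays, the distal small intestine control of pair 21 had a median r of 0.677 with the other arrays, against 0.745 to 0.772 in its group. Neighbouring spots correlated at 0.452 on the colon control array of pair 23, against 0.0946 to 0.177 in its group. The colon IUGR array of pair 21 had an SD over probes of 0.46, against 0.33 to 0.35. Log2 ratios far from their group in distal small intestine were INHA at -0.49 in the control of pair 25, and in IUGR piglets PI3 at 1.01 (pair 25), PR39 at -0.33 (pair 4), LEPR at 0.94 and NPW at 0.20 (pair 12), and SRY at -0.37 (pair 21). In colon these were TNFSF4 at 2.02 in the IUGR piglet of pair 21, PI3 at 0.25 in that of pair 25, SCAMP1 at 0.41 and IL2 at -0.35 in that of pair 12, ACADS at 0.14 in that of pair 23, and MMP20 at -0.46 in the control of pair 23. Both values of PI3 come from the same IUGR piglet of pair 25.

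Between colon and distal small intestine 619 probes passed, PI3, INHA, PR39 and PLA2G1B among those with a name. Chance can be excluded, since 1 of 100 splits that exchanged the tissues of piglets, the real one, gave as many, and the highest of the others gave 1. A trend by position on the array is argued against as the whole cause, since 551 of the 619 (89.0%) stayed past the threshold once the local median was removed. A single pair as the cause is argued against too, since between 174 and 256 of the 619 stayed past it when 1 of the 4 pairs was left out. The tissue itself is left as a hypothesis, found and tested on the same arrays, and RNA quality, of which the tables hold no measure, was not tested.

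For the difference of the IUGR effect between the tissues, 2962 probes were at an unadjusted p under 0.05, with ITM2A the named gene of smallest p and 0 probes past the threshold in limma. Exchanging the members of pairs makes 8 splits, too few for a share under 0.05, of which 2 gave as many, with 3840 in the highest of the others, the split that turned pair 25, where 664 probes passed. Without pair 25 there are 4 splits, again too few, of which 1 gave as many as the real 2014, with 0 in the highest of the others; any 4 piglets against 4 without the block gave as many as the real 2114 in 5 of 35 splits, with 3107 in the highest of the others, so chance cannot be excluded. A trend by position is argued against by the 3473 probes at this level with the local median removed, whereas a contribution of the wide colon IUGR array of pair 21 cannot be excluded, with 1736 without that pair and 1402 to 5246 with any 1 pair left out. That IUGR differs in its effect between the tissues stays open, as does a structure of these few arrays unrelated to IUGR, which was not tested.

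PAG6, ASIP, CEND1, PSMB8 and LTA, 5 neighbouring named spots, were all higher in IUGR distal small intestine, with a median of 0.18. A trend by position may account for part of this, since the 28 unnamed spots around them had a median of 0.099 (SD 0.086), 26 of them above 0, and with the local median removed the median of the 5 was 0.068. The bound of 50% for that test was set after the surrounding values had been seen and was passed narrowly. A change of ASIP is argued against by its other 3 spots, which had a median of -0.0086 and lay between -0.012 and 0.049, against 0.18 at the spot among the 5. A change of PAG6 stays open, at 0.16 with the local median removed.

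For IUGR in distal small intestine, the real split gave 536 probes at an unadjusted p under 0.05 and 0 past the threshold in limma. Exchanging the members of pairs gave as many in 26 of 32 splits, with 2625 in the highest of the others, so chance cannot be excluded. Any 6 arrays against 6 without the block gave as many as the real 535 in 71 of 100 splits, with 3026 in the highest of the others. Another split of each kind put 162 and 156 probes past the threshold, which points to a structure of the samples apart from IUGR, but only 2 of 31 and 5 of 99 put any there, where chance alone gives about 1 in 20, and the cause was not tested.

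For IUGR in colon, the real split gave 590 probes at an unadjusted p under 0.05 and 0 past the threshold in limma. Exchanging the members of pairs makes 16 splits, too few for a share under 0.05, of which 12 gave as many, with 4315 in the highest of the others. Any 5 arrays against 5 without the block gave as many as the real 417 in 73 of 100 splits, with 5250 in the highest of the others, so chance cannot be excluded. Another such split put 1886 probes past the threshold, which points to a structure of the samples apart from IUGR, but only 2 of 99 put any there, and the cause was not tested.

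For sex in distal small intestine, 2 of 100 splits of 6 arrays against 6 gave as many probes past the threshold as the real 1, with 1 in the highest of the others, but these splits broke up the labelled pairs and so cannot exclude chance. With as many pairs of 1 sex and of both sexes as in the real split, 5 of all 180 gave as many (4 in a first draw of 100), with 109 in the highest of the others. That share is under 0.05. With a real count of 1, however, it only asks whether a split put any probe past the threshold, and it is 1 of several such tests. Chance is therefore not clearly excluded. For sex in colon, 4 of 100 splits of 6 arrays against 4 that broke up the pairs gave as many probes at an unadjusted p under 0.05 as the real 2724, with 3720 in the highest of the others. With the pairs kept, 6 of all 120 did (5 in a first draw of 100), with 4472 in the highest of the others, so chance cannot be excluded. Other splits in colon put up to 306 and 85 probes past the threshold where the real one put 0 in limma, which points to a structure of the samples, but only 5 of 99 and 4 of 119 put any there, and the cause was not tested.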

How the results depend on the processing

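Removal of the median of each print block and of the local median was chosen after the data were seen, and the 7 gene lists after the probe names but before any value of a named gene. All 19 alternatives for IUGR in distal small intestine and all 18 in colon left limma at 0 probes past the threshold, against 536 and 590 at an unadjusted p under 0.05 with the values as reported. Over these alternatives 1.49% to 7.23% and 1.47% to 11.4% of the probes were at that level. Without the replicate block, IUGR still gave 0 probes in each tissue (535 and 417 at an unadjusted p under 0.05), the difference of the IUGR effect gave 0 (2114 at that level), and the tissues gave 1000. The tissues gave 974 with array weights and 177 to 286 with 1 pair left out, which also leaves fewer piglets, against 433 to 808 in the other 6 alternatives. In all 12, between 56.2% and 67.2% of the probes past the threshold were higher in colon. The difference of the IUGR effect gave 0 to 2014 with 1 pair left out, the 2014 without pair 25, and 0 in the other 8 alternatives. Gene lists past the threshold for IUGR in distal small intestine ranged from 0 to 1 with 1 pair left out, the 1 being cytokines and chemokines without pair 11, and fry gave 2 lists for the difference of the IUGR effect. With differences in either direction, fry gave 0 lists for IUGR in each tissue, where camera gave 0 too, 2 between the tissues and 3 for the difference of the IUGR effect, against 0 with camera. The correlation of the IUGR effects of the tissues was 0.131 in 1 division into different pairs, against -0.413 in the shared pairs, and the cause was not tested. Weights kept their direction as ratios. Over 54 gene and comparison combinations and 756 alternatives, 726 kept their side of the threshold, 12 were weaker, all PR39 or PLA2G1B between the tissues, 18 were stronger and 0 reversed. Only 4 of the 54 passed with the values as reported, so most of the 726 did not pass in either fit. Of these 4, PR39 was weaker in 5 of 11 alternatives, PLA2G1B in 7 of 12, and PI3 and INHA in 0 of 12 each. Most of the 54 were picked for the same sign in every pair or piglet, so leaving out a pair could hardly reverse them. The stronger ones included CD4, IL2, SULT1E1, GHRL and LIF between the tissues without the block, and ITM2A, CDKN2B, NPW, SRY, PDCD1LG2, GAD2 and ACADS without pair 25. The causes were not tested, apart from the smaller number of pairs in left-out fits. No channel intensities are in the table, so what the signal over background limits could not be computed.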

Other observations

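All tests of the hypotheses in this part were chosen after the result was seen.

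Some further genes of the lists, chosen after their values were seen, lay on the same side in most piglets without passing over all probes. In colon against distal small intestine, RXFP4, the receptor of an insulin-like peptide hormone of the hindgut, was 0.18 higher (7 of 8 piglets), KCNN4 0.22 higher (6 of 8), the interferon IFN-DELTA-1 0.18 higher (7 of 8) and MYOC 0.24 higher (7 of 8). The G protein subunit GNAS differed by -0.25, the death receptor FAS by -0.20 and the hormone precursor POMC by -0.11, each lower in colon in 7 of 8 piglets. For the difference of the IUGR effect between the tissues, UTS2 was 0.68 more positive in colon, the lymphocyte chemokine receptor CXCR6 0.37, KCNN4 0.32 and the defensin DEFB1 0.26, each in 4 of 4 pairs. Such agreement over 4 pairs is common by chance.

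A hypothesis is that ITM2A may differ in opposite ways between IUGR and control piglets in the tissues. With a difference of 0.78, its limma adjusted p over the named probes alone was 0.0199 with the deposited values, 0.0211 after centring and 0.00644 with the local median removed. After quantile normalization the difference was 0.70 and the adjusted p over the named probes 0.0936, so the hypothesis did not meet its criterion of passing in all 4 forms of the values. The 95% interval stayed above 0 in each form, from 0.41 to 0.99 after quantile normalization. ITM2A was picked for its small p on these same arrays, so such an interval could hardly hold 0. That interval therefore cannot decide for or against the difference. Over all probes the adjusted p lay between 0.194 and 0.416. Over all pairs of each tissue the effect was 0.20 in colon and -0.18 in distal small intestine, with 95% intervals that held 0.

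Another hypothesis was that PSMB8 may be higher in IUGR piglets in both tissues. With the tissues averaged in the 4 pairs with both and the 1 measured tissue taken in the other 3, PSMB8 was 0.21 higher (SE 0.065, 6 of 7 pairs), with an adjusted p of 0.616 over the named probes in limma. The hypothesis did not meet its criterion of passing there. The 95% interval of 0.069 to 0.35 lay above 0, but PSMB8 was picked for being higher in both tissues on these same arrays. That interval therefore cannot decide for or against a difference. In that fit 0 of 19700 probes passed over all probes, with 361 (1.83%) at an unadjusted p under 0.05. Its neighbouring spots PAG6 (0.21, 7 of 7 pairs, adjusted p 0.408) and ASIP (0.17, 5 of 7 pairs) were higher too, so a trend by position may account for part of it. With the local median removed PSMB8 differed by 0.068 in distal small intestine and 0.082 in colon.

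The unnamed probe 9480 may stand for a transcript at a higher level in females. In pair 23, whose piglets had no array of distal small intestine, where the probe was picked, the female was at 0.36 and the male at -0.24 in colon, a difference of 0.60. A trend by position is argued against, since with the local median removed the lowest female lay 0.26 above the highest male in distal small intestine and 0.33 in colon, and the difference in distal small intestine was -0.54 (adjusted p = 0.0308). The gene of the probe is not known from the tables at hand, and the test reuses the arrays in which the sexes were compared.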
